A study of Drosophila melanogaster with 4 samples.

How the data were processed

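RNA was measured by sequencing in intestinal stem cells of adult Drosophila melanogaster, the dividing cells that renew the gut epithelium. The cells had been sorted by flow cytometry from pools of 100 dissected guts per library. RNA interference against Piwi, or against the foreign fluorescent protein mCherry as the control, had been expressed for 7 days at 29 °C. The series holds 4 libraries, 2 per group. The libraries came from separate pools per the labels, so the p-values measure the spread between pools of flies. RNA was extracted with Trizol and libraries were made with the TruSeq RNA kit, per the labels' protocols. The labels of the mCherry RNAi libraries also name a yw source, and how the genetic backgrounds of the groups relate is not given in the sources used here.

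The authors deposited one table of FPKM values (fragments scaled to transcript length and to the mapped fragments of the library), with a column per library and a row per gene. The column names of that table are those of Cufflinks tracking output, per the file headers, and TopHat and Cufflinks are named in the submitters' processing notes. Their versions, the genome build, the annotation, the strand setting and any scaling between libraries are not given in the sources used here. The table has 15495 rows, of which 14845 carry an identifier found in the gene name table used here, and 4508 are listed at 0 in every library. All 37 mitochondrial rows are listed at 0 in every library, so an exact 0 was read only as a listed value. Transposable elements, the classic targets of Piwi, and the replication-dependent histone genes had no matching row and were not analysed here.

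FPKM values are not counts and were not treated as such. The smallest nonzero values of genes with a single annotated transcript of at least 800 nt fell on regular steps, after an effective length of 130 nt less than the transcript, so the value of a single fragment was estimated per library. This gave depths of about 2060000 and 2100000 fragments for the mCherry RNAi libraries and 1630000 and 2310000 for the Piwi RNAi libraries. Between 86.1% and 89.7% of low values lay within 0.1 of a whole number of fragments, against 20% by chance. Fragment numbers given for piwi rest on these estimates, and the interval made from them covers counting error only. That effective length cannot be used for the small nucleolar and Cajal body RNAs, some of which are shorter than 130 nt. Their values were divided instead by a unit, the lowest value above 1 FPKM of such RNAs of the same transcript length in the group, scaled to the depth of each library. Whether the unit is a single fragment was not tested, and for lengths with a single row it comes from that row itself.

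The comparison was a limma-trend fit (lmFit and eBayes with a trend) on log2(FPKM + 1), two-sided, over the 8313 genes with a mean of at least 1 FPKM. Adjusted p-values are from limma with Benjamini-Hochberg adjustment over these genes, with a threshold of 0.05. Log2 differences are Piwi RNAi minus mCherry RNAi on the log2(FPKM + 1) scale, which understates the change of low genes, and errors beside them are standard errors. With 2 libraries per group the fit had 2 residual and 2.86 prior degrees of freedom. The fit was tested on simulated data with the means of these 8313 genes. Genes were drawn independently, and the spread of each was averaged over genes of like mean level, so differences in spread between such genes were left out. Changes were placed only in genes with a mean of at least 5 FPKM. The fit called 6% of genes changed 2-fold, 38.0% of those changed 4-fold, 86.0% of those changed 8-fold and 90.0% of those changed 16-fold. These were 3, 19, 43 and 45 genes of 50 each, beside 12 calls among 8113 unchanged genes.

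The test, the filter, 29 gene lists, the rule for named genes and most alternatives were set before the data were examined. Of the lists, 26 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The named genes were, per direction, the 12 with the largest difference among called genes with a mean of at least 5 FPKM in the higher group and no overlap between the groups. The same rule was applied again to genes with a name other than a CG or CR number. The rule also took piwi, esg, Dl and Sox21a and the tested members of each list with the smallest p, 4 for lists past the set test and 2 for the others. TER94, p47, Pomp, Prosalpha5, Pros28.1, Rpn1, Nacalpha, Ef1alpha48D, Rack1, npf, alphaTry, CCHa2 and CG17145 were named after their values were seen. So was the list of proteasome subunits.

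The alternatives were other pseudocounts (0.1 and 5), no filter on low values or a mean of at least 5 FPKM, quantile normalization, scaling by the median of ratios, eBayes without a trend or robust, the replicate number as a block, each library left out, and other thresholds. An adjustment of each library for a loess trend on transcript length, and a fit without small nuclear and nucleolar RNA rows, were added after the data were seen. Transcript lengths and the order of genes along chromosomes came from the BDGP6 annotation, and no coordinates are given because the build of the deposited table is not known here. Analyses used R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.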

Results

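The transcriptomes of sorted intestinal stem cells were compared after 7 days of RNA interference against Piwi or against mCherry, to ask what loss of this Argonaute protein changes in the cells that renew the fly gut. Each group had 2 libraries, each from a pool of 100 guts. FPKM values summed to 1044487 and 1050749 in the mCherry RNAi libraries and to 900475 and 928972 in the Piwi RNAi libraries, and the estimated depth was 1630000 to 2310000 fragments. Between 9299 and 9980 genes had a value above 0 in a library. Across the tested genes, log2 values of the Piwi RNAi libraries correlated at r = 0.944 and those of the mCherry RNAi libraries at r = 0.888. mCherry RNAi replicate 1 stood apart, with r = 0.843 and 0.858 to the Piwi RNAi libraries, where mCherry RNAi replicate 2 reached 0.905 and 0.925. These correlations are across genes, which are not independent replicates.

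The targeted gene, piwi (FBgn0004872), was near the detection limit in all libraries. It had 0.495 and 1.94 FPKM in mCherry RNAi replicates 1 and 2, and 0.208 and 0.442 FPKM in Piwi RNAi replicates 1 and 2. These values correspond to about 3 and 12 fragments against 1 and 3. Pooled over libraries, the ratio of Piwi RNAi to mCherry RNAi was 0.282, with an exact 95% Clopper-Pearson interval of 0.068 to 0.884 that covers counting error only. The mean lay under the filter, so piwi was not tested. Its log2 difference was −0.67, and without mCherry RNAi replicate 2 it was −0.18, so the size of the knockdown rests largely on that library.

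Between the Piwi RNAi and mCherry RNAi libraries 98 of 8313 genes changed, 51 higher and 47 lower in Piwi RNAi. The higher genes included 24 subunits of the proteasome, the complex that degrades ubiquitinated proteins, 2 of their paralogs and 7 genes that lie side by side on chromosome arm 3L. The lower genes included 29 ribosomal protein genes, 10 rows of small nucleolar or Cajal body RNAs and Orcokinin, a neuropeptide gene of the gut. The median log2 difference of all tested genes was 0.37, and it was −0.02 after scaling by the median of ratios. Medians of lists that passed a test are therefore also given relative to that of all tested genes. After scaling by the median of ratios, the only higher call was the antisense RNA gene CR43875 of the 3L genes. The lower calls were then all small nucleolar or Cajal body RNA rows, which may rest on few fragments. That scaling left 1 higher and 7 lower calls, quantile normalization left 25 and 10, and leaving out any library left 0 limma calls, with 619 to 3195 genes at an unadjusted p under 0.05.

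**Figure D1:**
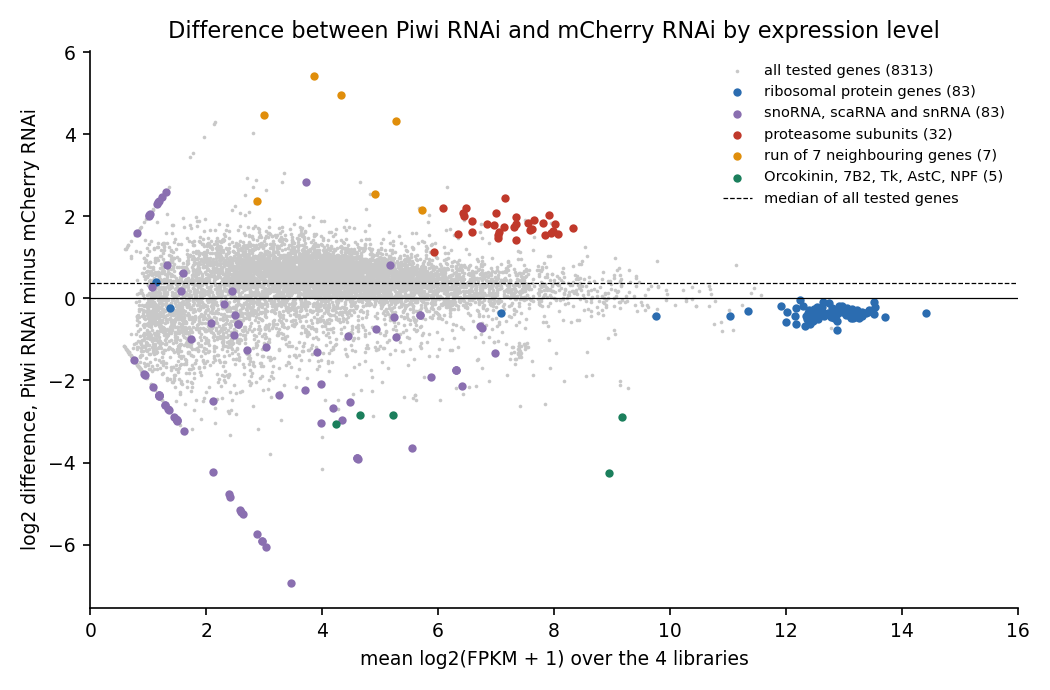
Log2 difference between Piwi RNAi and mCherry RNAi (vertical axis) against the mean log2(FPKM + 1) over the 4 libraries (horizontal axis), with a point per tested gene and gene groups in colour. The 32 proteasome subunits lie between 1.14 and 2.44, above the dashed median of all genes at 0.37, and most ribosomal protein genes lie below 0 at the right, though their median is 0.00 with quantile normalization.

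All 32 tested subunits of the proteasome were higher in both Piwi RNAi libraries than in both mCherry RNAi libraries, with a median log2 difference of 1.76, or 1.40 relative to all genes. Of these, 24 rose at an adjusted p under 0.05. All 32 did when adjusted over the list alone, but the list was drawn up after the leading genes were seen, so this is no separate support. For comparison, 51.5% of all tested genes lay higher in both Piwi RNAi libraries, where chance alone gives 16.7%. The core particle subunit Prosalpha5 (FBgn0016697) rose 3.75-fold, from 102.8 ± 1.44 to 388.7 ± 12.1 FPKM (SD, n = 2 per group; log2 difference 1.91 ± 0.13; adjusted p = 0.0313). In the regulatory particle, Rpn3 rose by 2.21 ± 0.19, Rpn2 by 2.20 ± 0.22 and Pros54, the ubiquitin receptor Rpn10, by 2.09 ± 0.18 on the log2 scale. The largest and smallest differences, 2.44 for Pros28.1 (adjusted p = 0.0565) and 1.14 for Rpn1 (adjusted p = 0.134), did not pass.

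Genes known to act with the proteasome were looked up after their values were seen and were not tested as a group. CG2046, the fly counterpart of the proteasome assembly chaperone PSMG1, rose by 2.54 ± 0.21, TER94, the segregase that extracts ubiquitinated proteins, by 1.92 ± 0.21, and its cofactor p47 by 1.55 ± 0.17. Pomp, a maturation factor of the core particle, had a log2 difference of 1.82 with an adjusted p of 0.0565. The paralogs Rpt6R and Rpt3R, which have restricted expression, also rose. Rpt6R had 0.737 and 0.724 FPKM in mCherry RNAi and 21.4 and 34.8 FPKM in Piwi RNAi. Rpt3R was listed at 0 in both mCherry RNAi libraries and had 12.4 and 16.5 FPKM in Piwi RNAi. Reads shared with Rpt6 and Rpt3 leave both levels uncertain. Rpt6 (Pros45) and Rpt3 were themselves 2.69-fold and 3.35-fold higher in Piwi RNAi. A constant share of their reads would rise by those factors, which argues against it as the whole cause of the larger rise of Rpt6R and Rpt3R. Proteasome subunits made up 24 of the 51 higher genes against 32 of the 8313 tested (one-sided Fisher's exact test, p = 1.27e-49). Fisher's test takes genes as independent, though, and the list was drawn up after the leading genes were seen. Its camera p was 6.95e-17 at the preset correlation and p = 0.191 with an estimated correlation of 0.748, fry gave p = 0.0089, and scaling by the median of ratios left 0 of the 24 limma calls, with a median of 1.34 and a smallest adjusted p of 0.0563.

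Of the genes that rose, 7 lie in a single stretch of chromosome arm 3L. The serpin genes Spn77Ba, Spn77Bb and Spn77Bc, which encode inhibitors of serine proteases, rose by 5.41 ± 0.60, 4.47 ± 0.36 and 2.38 ± 0.26 on the log2 scale. Between and beside them, CG6434 rose by 4.94 ± 0.47, the antisense RNA gene CR43875 by 4.33 ± 0.32, Rbbp5, a subunit of histone H3K4 methyltransferase complexes, by 2.53 ± 0.30, and Snap, the SNARE disassembly factor alpha-SNAP, by 2.16 ± 0.23. Spn77Ba (FBgn0262057) had 2.86 and 0.264 FPKM in mCherry RNAi and 73.7 and 117.9 FPKM in Piwi RNAi (adjusted p = 0.0378). These 7 genes follow each other without a gap among tested genes. The 10 tested genes on each side held 0 calls and had a median difference of 0.43, close to that of all genes. Of the 7, CR43875 overlaps Snap and Spn77Ba, so reads cannot be assigned between these 3 without knowledge of the strand setting, and the other 4 overlap no called gene of the stretch. Scaling by the median of ratios left 1 of the 7 calls, with a median of 3.93 against 4.33.

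**Figure D2:**
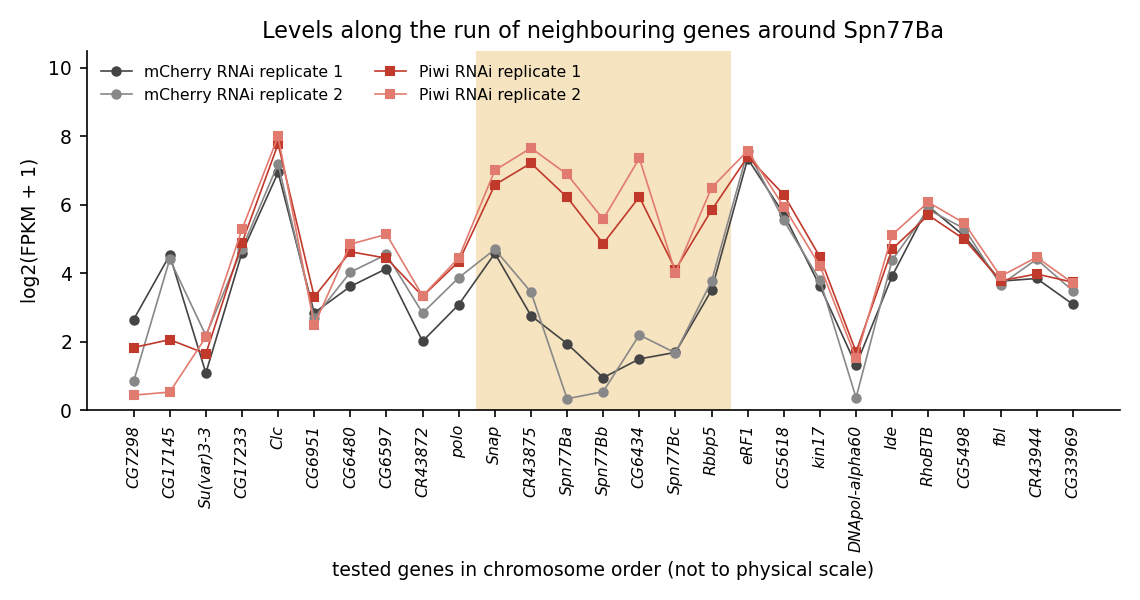
Log2(FPKM + 1) of consecutive tested genes in chromosome order around Spn77Ba, with a line per library (circles mCherry RNAi, squares Piwi RNAi). In the shaded stretch of 7 genes both Piwi RNAi libraries lie above both mCherry RNAi libraries. No gene on either side passed the test, though CG17145 had 22.2 and 20.3 FPKM in mCherry RNAi and 3.19 and 0.449 FPKM in Piwi RNAi.

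Among the other higher genes were a pair of nuclease and DNA repair genes. Ku80, which binds DNA ends in non-homologous end joining, rose by 2.53 ± 0.28 (adjusted p = 0.0378), from 1.66 ± 0.177 to 14.3 ± 0.86 FPKM (SD, n = 2 per group). DNaseII, an acid nuclease of the lysosome, rose by 2.83 ± 0.23. The uncharacterised genes CG15073 and CG34253 rose by 3.04 and 2.83, and CR18854 rose by 2.72. CG43117 was listed at 0 in both mCherry RNAi libraries and had 18.9 and 17.2 FPKM in Piwi RNAi (adjusted p = 0.0313). Ku80 was the only riser in the DNA damage and apoptosis list, with 29 of 30 members not past the test, and Irbp, its partner Ku70, had a log2 difference of 1.12 with an adjusted p of 0.134.

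Of the peptide hormone genes of enteroendocrine cells, the secretory cells of the gut epithelium, Orcokinin fell and others had lower values that did not pass. Orcokinin (CG13565, FBgn0034935) fell 18.9-fold by group means, from 1694 and 2739 FPKM to 83.5 and 151.3 FPKM (log2 difference −4.25 ± 0.37; adjusted p = 0.0313). Tachykinin (Tk) had a log2 difference of −2.84 (adjusted p = 0.0573), Allatostatin C (Ast-C) −2.83 (adjusted p = 0.0657), neuropeptide F (npf) −2.89 (adjusted p = 0.108) and the secretory chaperone 7B2 −3.06 (adjusted p = 0.0573). CCHa2 had 14.1 and 3.24 FPKM in mCherry RNAi and 5.36 and 1.26 FPKM in Piwi RNAi, so its groups overlapped. Of 18 tested enteroendocrine genes, 1 fell and 17 did not pass, and 7 were lower when adjusted over the list alone. The list median was −1.18, or −1.54 relative to all genes, and the list was lower by camera (adjusted p = 7.29e-11), though not with an estimated correlation (p = 0.154). Nplp2, a neuropeptide-like precursor outside the list, fell by 2.10 ± 0.25 on the log2 scale. Orcokinin's call was lost with median of ratios scaling (adjusted p = 0.0563), after length adjustment (0.0544), with no filter on low values (0.122), without a trend (0.165) and with each library left out. Its log2 difference ran from −4.67 to −3.82 with a library left out. The list was lower by camera at the preset correlation with each pseudocount, filter, scaling and library left out, and its median ranged from −0.63 at a pseudocount of 5 to −2.75 at a mean of at least 5 FPKM.

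Of 83 tested ribosomal protein genes, 82 had lower values, 29 fell, 54 did not pass and 75 were lower when adjusted over the list alone. Their median log2 difference was −0.36, or −0.73 relative to all genes. RpS26 fell from 9835 ± 157 to 5812 ± 116 FPKM (SD, n = 2 per group; log2 difference −0.76 ± 0.05; adjusted p = 0.0313), and RpS12, RpL37A and RpS15Aa fell by 0.66, 0.64 and 0.63 on the log2 scale. Of other translation genes, picked after their values were seen, 3 fell, with log2 differences of −0.79 for Nacalpha of the nascent chain-associated complex, −0.73 for the elongation factor Ef1alpha48D and −0.62 for the ribosomal scaffold Rack1, while the 35 genes with eIF symbols had a median of 0.25 and 0 limma calls (camera adjusted p = 0.619). The ribosomal protein list was lower by camera (adjusted p = 2.20e-23) but not with an estimated correlation (p = 0.0782). Quantile normalization, which forces equal upper ends on the libraries, brought its median to 0.00, with 41 of the 83 genes below 0, and left 1 call. The list did not pass camera there (adjusted p = 0.433). Median of ratios scaling left 0 limma calls at a median of −0.78, with the list lower by camera (adjusted p = 7.12e-26). An adjustment for transcript length brought the median to −0.18 with 0 limma calls.

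Small nucleolar and Cajal body RNAs gave 10 further lower calls, of which 9 were listed at 0 in both Piwi RNAi libraries. Of 83 tested small nuclear, nucleolar and Cajal body RNA rows, 73 did not pass and 16 had positive differences. Of 180 small nucleolar and Cajal body rows, 35 and 52 were above 0 in mCherry RNAi replicates 1 and 2, and 15 and 34 in Piwi RNAi replicates 1 and 2. snoRNA:Psi18S-1820 had 79.0 and 182.6 FPKM in mCherry RNAi, and snoRNA:Psi28S-1060 had 75.7 and 56.3 FPKM. snoRNA:Or-CD2, snoRNA:Psi28S-2876, snoRNA:Or-aca4, snoRNA:Psi28S-3405d and scaRNA:mgU2-41 had between 25.4 and 52.6 FPKM in mCherry RNAi. snoRNA:Psi18S-1377e and snoRNA:Psi28S-1837b were listed with identical values, 29.5 and 116.8 FPKM, so their reads may not be separable. These 9 had transcript lengths of 122 to 162 nt. Their mCherry RNAi values were 1 to 7.06 times the lowest nonzero value of such RNAs of the same length in the group. That value may be as little as a single fragment. At 140 nt the nonzero mCherry RNAi values lay near whole multiples of it, as single fragments would. There, snoRNA:Psi28S-3405d was at 1 and 1.01 times it and snoRNA:Or-CD2 at 2 and 2.02 times. If it is a single fragment, calls on so few fragments carry little weight. snoRNA:Psi18S-110, with 191.2 and 162.4 FPKM against 35.4 and 44.0 FPKM, had 7 and 6.05 times the lowest value of its length against 1 and 1.76. After length adjustment 0 of the 10 passed the limma test (9 at an unadjusted p under 0.05). The difference of snoRNA:Psi18S-110 went from −2.13 to −0.69 on the log2 scale (adjusted p = 0.548) and the median of the 10 from −5.50 to −4.06, with a smallest adjusted p of 0.0544. With 9 of the 10 at 0 in Piwi RNAi, the size of these differences depends on the pseudocount, and their median was −8.79 at 0.1 and −3.30 at 5. Median of ratios scaling left 7 of the 10 calls, a fit without a trend 4, and each library left out 0 by limma, with 10 at an unadjusted p under 0.05. Besides these, CG13511 fell by 2.49 ± 0.29 and Dic1, a mitochondrial dicarboxylate carrier, fell by 1.91 ± 0.22 on the log2 scale.

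Markers of the stem cells themselves were detected in both groups and did not pass the test. The progenitor factor esg (FBgn0001981) had 239.7 and 301.9 FPKM in mCherry RNAi and 415.9 and 378.5 FPKM in Piwi RNAi (log2 difference 0.56; adjusted p = 0.153). The Notch ligand Dl had a difference of 0.09, which was −0.24 after scaling by the median of ratios and −0.041 without Piwi RNAi replicate 1, and Sox21a had 0.50 (adjusted p = 0.218). Of 22 stem cell and enteroblast genes 0 passed the limma test, and 3 were higher when adjusted over the list alone, led by klu at 1.40 (adjusted p = 0.0594) and zfh2 at 1.26. The list median of 0.43 was 0.07 above that of all genes (camera adjusted p = 0.173), and it was 0.26 and 0.70 without mCherry RNAi replicates 1 and 2.

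**Figure D3:**
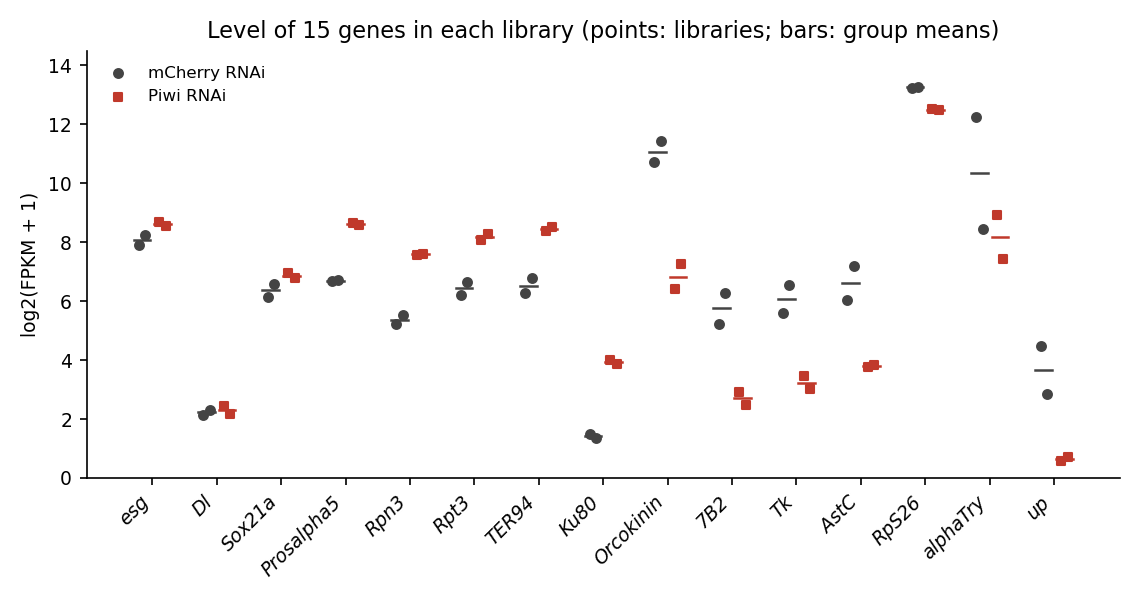
Log2(FPKM + 1) of 15 genes in each of the 4 libraries (circles mCherry RNAi, squares Piwi RNAi; bars are group means). The proteasome genes Prosalpha5, Rpn3 and Rpt3 are higher and Orcokinin, 7B2, Tk and AstC lower in both Piwi RNAi libraries, esg, Dl and Sox21a differ by 0.56, 0.09 and 0.50, and alphaTry differs most between the mCherry RNAi libraries, at 4906 and 349 FPKM.

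Markers of mature enterocytes and of visceral muscle were high in mCherry RNAi replicate 1. The enterocyte list of 50 genes had a median difference of −0.91, or −1.28 relative to all genes (camera adjusted p = 1.26e-09; p = 0.330 with an estimated correlation) and 0 limma calls. Its median was 2.49 lower in mCherry RNAi replicate 2 than in replicate 1, and the Piwi RNAi libraries lay 0.29 above mCherry RNAi replicate 2. The digestive protease gene alphaTry had 4906 FPKM in mCherry RNAi replicate 1 but 349 FPKM in replicate 2, against 483.8 and 172.5 FPKM in Piwi RNAi. Myo31DF, Lip3, Jon65Aiv and Mal-A7 had log2 differences of −0.64, −1.70, −2.02 and −1.64, with 0 past the test. The visceral muscle list of 16 genes had a median of −1.25, or −1.61 relative to all genes (camera adjusted p = 4.97e-04; p = 0.253 with an estimated correlation), with −3.03 for the troponin gene up, 1.77 for vn, 0.31 for Tm1 and −0.45 for Zasp52. Without mCherry RNAi replicate 1, the enterocyte list had a median of 0.29 and the muscle list 0.04 (camera adjusted p = 0.640 and 0.491), and at a mean of at least 5 FPKM the muscle list's call was lost too (adjusted p = 0.102).

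No tested gene of the small RNA pathways passed the test alone. The siRNA and miRNA list had a median of 0.95, or 0.58 relative to all genes (camera adjusted p = 0.0388; p = 0.391 with an estimated correlation). Of its 11 genes 0 passed alone and 6 were higher when adjusted over the list alone, with 1.55 for the exportin Ranbp21, 0.95 for gw, 0.96 for loqs and 1.33 for r2d2. The list's call was lost without mCherry RNAi replicate 1 (adjusted p = 0.170), Piwi RNAi replicate 1 (0.0668) or Piwi RNAi replicate 2 (0.0667), at a mean of at least 5 FPKM (0.0782) and after length adjustment (0.094). Of 16 tested piRNA pathway genes 0 passed and 5 were higher when adjusted over the list alone, with 1.38 for CG9754, the silencing factor Panx, and 1.41 for the helicase gene armi (median 0.78; camera adjusted p = 0.202). Heterochromatin and silencing genes had a median of 0.55 over 25 genes (adjusted p = 0.129), with 1.17 for Su(var)3-7 and 1.25 for E(z).

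No member of the fixed stress and metabolic lists passed the test alone. Relative to the median of 0.37 of all tested genes, glycolysis was at 0.37 and the unfolded protein response at 0.02. Mitochondrial respiration was at −0.13, lipid metabolism at −0.30 and heat shock at −0.43. The oxidative stress and detoxification list of 33 genes was lower by camera (adjusted p = 0.0388; p = 0.210 with an estimated correlation), with a median of −0.04 that was −0.40 relative to all genes. Its members went both ways, with 1.24 for GstE1, 0.68 for Trxr-1 and 1.23 for Cyp6a17 but −1.28 for GstD4, and the call was lost without mCherry RNAi replicate 1 (adjusted p = 0.525) or Piwi RNAi replicate 2 (0.107), with no filter on low values (0.0976), with quantile normalization (0.0823) and after length adjustment (0.094). Glycolysis had a median of 0.74 over 15 genes (adjusted p = 0.155), with 8 higher when adjusted over the list alone, led by Tpi at 1.17 and Pgi at 1.23, and its median was 0.45 without Piwi RNAi replicate 2. Heat shock and chaperone genes had a median of −0.06 over 23 genes (adjusted p = 0.155), with 1.03 for Hsp27 (adjusted p = 0.0594) and 0.90 for Hsp83, and its median ran from −0.38 without Piwi RNAi replicate 1 to 0.22 without Piwi RNAi replicate 2. The unfolded protein response had 0.39 over 19 genes (adjusted p = 0.202), with 0.94 for Cnx99A and 0.93 for Edem1. Mitochondrial respiration had 0.23 over 40 genes (adjusted p = 0.788), with 0.29 for cype and 0.51 for blw, but with median of ratios scaling its median was −0.19 and it was lower by camera (adjusted p = 0.0232). Lipid metabolism had 0.06 over 23 genes (adjusted p = 0.155), with 1.17 for Mtpalpha and −0.998 for fu12.

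Signalling and proliferation lists did not pass camera in the planned fit. Their medians below are to be set beside 0.37 for all tested genes. Relative to it, the cell cycle list was at 0.26, DNA damage 0.19, EGFR and MAPK 0.27, Notch 0.03, insulin and TOR 0.02 and JNK 0.002. The Wnt, BMP and Hippo list was at −0.11, JAK-STAT at −0.28 and antimicrobial peptides at −0.36. The cell cycle list had a median of 0.62 over 49 genes (adjusted p = 0.0906), with 1.17 for E2f and 1.57 for scra, and the DNA damage and apoptosis list 0.55 over 30 genes (adjusted p = 0.0906). The cell cycle list was higher by camera with quantile normalization (adjusted p = 0.0191), median of ratios scaling (0.0153), no filter on low values (0.0112), and without mCherry RNAi replicate 2 (0.00282, median 1.11) or Piwi RNAi replicate 2 (0.0131). It did not pass without mCherry RNAi replicate 1 (median 0.28, adjusted p = 0.726), without Piwi RNAi replicate 1 (0.326), at a mean of at least 5 FPKM (0.228), after length adjustment (0.120) or, in the planned fit, with an estimated correlation (p = 0.658). The DNA damage list was higher with quantile normalization (adjusted p = 0.0191) and no filter (0.0279), but not without mCherry RNAi replicate 1 (0.525) or, in the planned fit, with an estimated correlation (p = 0.309). Medians were 0.09 over 10 JAK-STAT genes (adjusted p = 0.788; hop 1.38, Su(var)2-10 0.55) and 0.64 over 17 EGFR and MAPK genes (adjusted p = 0.219; sty 0.83, Ras85D 0.79). They were 0.37 over 13 JNK and wound genes (adjusted p = 0.973; slpr 0.85, msn 0.34) and 0.39 over 18 Notch genes (adjusted p = 0.264; N 0.78, HLHmgamma 1.18). They were 0.25 over 23 Wnt, BMP and Hippo genes (adjusted p = 0.738; arm 0.59, fz2 0.72) and 0.38 over 15 insulin and TOR genes (adjusted p = 0.452; Tor 0.82, Rheb 0.50). Antimicrobial peptide and IMD genes had 0.01 over 18 genes (adjusted p = 0.129), with 0.75 for pirk and −0.59 for PGRP-LB. Of these medians, that of JAK-STAT was −0.051 without Piwi RNAi replicate 1 and 0.30 without mCherry RNAi replicate 2, JNK 0.22 without mCherry RNAi replicate 1, Wnt, BMP and Hippo 0.42 without Piwi RNAi replicate 2, insulin and TOR 0.21 without Piwi RNAi replicate 1 and antimicrobial peptides −0.059 without mCherry RNAi replicate 1 and 0.19 without mCherry RNAi replicate 2.

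Genes of other tissues were mostly low. Medians were −0.09 over 6 hemocyte and fat body genes (adjusted p = 0.240; Sr-CI 2.33, Fbp1 −1.49), 0.06 over 5 trachea and neuron genes (adjusted p = 0.794; btl 1.28, elav 0.63) and −0.17 over 6 Malpighian tubule, crop or hindgut genes (adjusted p = 0.302; drm 0.74, Irk2 −2.24). Only 3 germline genes reached the filter, with 0.26 for gcl and −0.46 for Cp18, and 3 genetic background markers, with 0.90 for w (adjusted p = 0.108) and −0.70 for ry. Irk2 had 38.2 FPKM in mCherry RNAi replicate 1 and 0.353 FPKM in replicate 2, and without replicate 1 its difference was 0.18 and its list's median 0.55. Likewise gcl was at −0.13 without mCherry RNAi replicate 1 and Cp18 at 0.80 without Piwi RNAi replicate 2, so these carry no direction. In these lists, 0 genes passed the limma test.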

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

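The list of proteasome subunits, the length adjustment and the fit without small RNA rows were chosen after the result was seen, and the other alternatives were planned. The count of changed genes moved most. Against 98, it was 0 with no filter on low values (2268 genes at an unadjusted limma p under 0.05), 167 at a mean of at least 5 FPKM, 35 with quantile normalization, 8 with median of ratios scaling, 4 without a trend, 209 with robust eBayes, 0 with each library left out in turn and 0 after length adjustment (1857 at an unadjusted p under 0.05). It was 65 when a 2-fold change was also required, 253 at an adjusted p of 0.1 and 2210 at an unadjusted p under 0.05. The 7 lower calls with median of ratios scaling and the 4 calls without a trend were all small nucleolar or Cajal body RNA rows. Leaving out a library leaves 1 residual degree of freedom and assumes that the lone library varies like the other group, which by itself can cost calls. How far this or the library left out accounts for the lost calls was not tested, nor was the cause of the other shifts. The replicate numbers are not known to pair the libraries (same-numbered libraries deviated together at r = 0.25 over genes), and with them as a block 194 genes, 31 proteasome subunits and 5 lists passed. Proteasome calls were 24 of 32, 17 with quantile normalization, and 0 with no filter, with median of ratios scaling, without a trend, after length adjustment and with each library left out, where 31 or 32 subunits still had an unadjusted limma p under 0.05. Of 26 lists, 6 were shifted, 0 by camera with an estimated correlation, 0 by fry (6 at an unadjusted p under 0.05), 2 to 10 with a library left out and 4 to 8 otherwise. The piwi difference was −1.43 at a pseudocount of 0.1 and −1.16 to −0.18 with a library left out, and the lowest correlation between libraries was 0.773 at that pseudocount. Lists that passed camera only away from the planned fit were cell cycle, DNA damage, heterochromatin (adjusted p = 0.0279 with no filter, 0.0399 without mCherry RNAi replicate 2), stem cells (0.0409 with quantile normalization), Malpighian tubule and lipid metabolism (0.0484 and 0.0399 without mCherry RNAi replicate 2), heat shock (0.00651 without Piwi RNAi replicate 1) and mitochondrial respiration (0.0232 with median of ratios scaling). With the block the siRNA and miRNA list was lost (0.0578). Quantile normalization left 41 of 83 ribosomal protein genes below 0, against 82 with median of ratios scaling. The medians of the lists of oxidative stress, heat shock, lipid metabolism, JAK-STAT, antimicrobial peptide, Malpighian tubule, hemocyte and trachea genes, from −0.17 to 0.09, turned sign with some library left out. Without mCherry RNAi replicate 1 the enterocyte median also did, from −0.91 to 0.29, and the visceral muscle median, from −1.25 to 0.04. Among the genes named in the report, those whose direction turned had not passed the limma test. With median of ratios scaling Tm1 was at −0.11, gcl −0.14, msn −0.087, cype −0.13 and Dl −0.24. With quantile normalization gcl was at −0.14 and Dl at −0.028, and Dl was at −0.11 after length adjustment. With a library left out, Irk2 ranged from −4.67 to 0.18, gcl from −0.13 to 0.66, Cp18 from −1.71 to 0.80 and Dl from −0.041 to 0.23. At 1630000 to 2310000 fragments per library, genes near 1 FPKM rest on a few fragments. The simulated fit recovered 6% of 2-fold changes, which were placed only in genes with a mean of at least 5 FPKM.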

Other observations

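The tests of scaling, of a common share of other cells, of fewer enteroendocrine cells, of the stretch around Spn77Ba as a region, of chance placement and of regrouped libraries, and the families of genes with shared symbols, were chosen only after the result was seen. Sorting 8313 genes into 53 families of at least 8 members by the letters of their symbols gave a wider picture. Only part of the families that passed camera at the preset correlation are described here. With an estimated correlation no family passed (smallest camera adjusted p = 0.705). Mitochondrial ribosomal proteins were higher by camera, with medians relative to all genes of 0.22 over 47 large-subunit genes and 0.30 over 26 small-subunit genes (adjusted p = 0.00754 and 0.0348, and 0.705 for both with an estimated correlation). Without mCherry RNAi replicate 1 their medians, not relative to all genes, were 0.39 and 0.33, from 0.59 and 0.67. Mediator subunits (relative median 0.50 over 24 genes), nucleoporins (0.40 over 21) and the EMC membrane insertase (0.42 over 10) were also higher by camera, at adjusted p of 0.00802, 0.00937 and 0.0209 (0.705 each with an estimated correlation), and without mCherry RNAi replicate 1 their own medians went from 0.86, 0.77 and 0.78 to 0.51, 0.46 and 0.50. Cytochrome P450 genes (relative median −0.56 over 53), GstD genes (−1.13 over 11) and tetraspanins (−0.76 over 24) were lower, at adjusted p of 7.11e-06, 4.74e-05 and 2.55e-04 (0.705 each with an estimated correlation). Without that library the P450 median itself was 0.12, from −0.20, and the GstD median −0.31, from −0.77. Apart from the P450 genes, each of the medians not taken relative to all genes kept its sign without that library. Without it the median of all tested genes was itself 0.27, so a median above 0 there says little about the higher families. The P450 median of 0.12 lay below that of all genes. Each family median kept its sign with quantile normalization and with median of ratios scaling. In the planned fit 0 single genes of these families passed the limma test. Of the families not described, the Jon genes, among them Jon65Aiv, were lower by camera (adjusted p = 0.00529), but their median turned sign. It was −0.74, and 0.66 without mCherry RNAi replicate 1.

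All 32 tested proteasome subunits were higher, 24 of them past the test, though the list did not pass camera with an estimated correlation (p = 0.191). Adjustment for transcript length, which removed a trend down to a median of −0.63 in genes of up to 500 nt, left the subunits at a median of 1.79 (median SE 0.22, from 1.76 and 0.19), and scaling by the median of ratios left them at 1.34 (median SE 0.14), with all 32 above 0 in both. The single calls ended just past the threshold, at smallest adjusted p of 0.0524 and 0.0563, where 27 and 26 subunits had an unadjusted p under 0.001 (27 before) but genes at that level numbered 89 and 114 (140 before), which raises adjusted p. A shared chromosomal region is argued against too, since 8.33% of the risen subunits had a called gene of another kind within the 2 nearest tested genes on each side. A candidate explanation is a coordinated response of proteasome genes in the Piwi RNAi cells, a hypothesis found and tested on the same data, and whether it follows from Piwi loss, the RNAi construct or the genetic background was not tested.

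The 7 neighbouring genes around Spn77Ba lay closer together than chance placement gives, since the share of random lists of called genes with as many called neighbours was 0.001, the smallest that 1000 lists can give. That count was chosen after the stretch was seen, and the 7 called genes with a called neighbour are those of the stretch, so the share describes it and is no separate support. Overlapping genes share reads, and with genes that overlap another of the list left out, 4 called genes had a called neighbour and the share was 0.007. Reads shared between overlapping genes are argued against as the whole cause, since 4 of the 7 genes overlap no other called gene there. A transgene insertion or linked strain difference in that region could not be tested, because the stretch was picked for its called genes, so that the 100% of its tested genes with a difference above 1 decides nothing. Release of the region from Piwi-dependent silencing was not tested either.

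The lower enteroendocrine genes were not removed by the length adjustment, which left the list median at −1.21. A single share of carried-over mature cells is argued against, because between the mCherry RNAi libraries the enteroendocrine list moved up as the enterocyte list moved down, 3.40 apart. Fewer enteroendocrine cells in the sorted pools could lower all hormones, and genes of at least 5 FPKM in mCherry RNAi had a median log2 ratio of −3.03. This and lower expression per cell cannot be told apart, since the libraries hold no count of cells. The 4 hormone genes without overlap between the groups were lower by 7.79-fold (npf) to 18.9-fold (Orcokinin) in group means, and the groups of CCHa2 overlapped.

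Ribosomal protein genes had a median relative to all genes of −0.50 after length adjustment, from −0.73. Only 2 other genes lay in the same FPKM range, Ef1alpha48D and Rack1, at −1.10 and −0.99 relative to all genes (median −1.04). Both are translation genes already named above, so high abundance and a role in translation cannot be told apart there. Of the 3 ways to group the 4 libraries into pairs, the real one gave 98 calls and the highest other 0, which is too few ways for a share under 0.05.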
